A study of Mus musculus with 16 samples.

How the data were processed

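Poly(A)-selected RNA from 16 mouse fat samples was sequenced: brown adipose tissue (BAT) and inguinal white adipose tissue (WAT), each at 30 °C and 5 °C, with 4 libraries per group. Groups and replicate numbers were taken from the sample titles and the housing temperature, which matched in all 16. In 4 of the 8 BAT libraries a further source label gave the opposite temperature, so the count of changed genes was also computed with the groups of that label and with the 4 libraries in which all labels matched. The labels do not say that each library came from a separate mouse, so the p-values measure the spread between libraries.

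The authors deposited a single table of raw counts, with 46078 Ensembl gene identifiers and 16 library columns of whole numbers. The submitters' processing notes name Trim Galore and TopHat without versions. The counting program, its strand setting, the genome build and the annotation are not given in the sources used here, so no coordinates are reported. Symbols came from a mouse annotation matched by identifier, which named 45143 identifiers and left 935 without a name. The unnamed identifiers held 0.0403 to 0.117% of the counts per library and stayed in every test.

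Depth was 54264023 to 71289020 counts per library. Intervals and floors given for single genes cover counting error only, since reads without molecular identifiers are not independent molecules. A gene with 0 counts in a group is reported against a floor of 3 counts over the group, and one with 1 to 3 counts with its exact 95% binomial (Clopper-Pearson) interval of the ratio.

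Libraries of one group were compared pairwise, and each of the 24 pairs differed by more than sampling noise (lowest chi-square per degree of freedom 21.4). Replicate numbers were not shown to pair the samples: the correlation of residuals across genes between equal numbers of different groups ran from -0.456 to 0.287, and equal numbers were not each other's best match throughout. Only BAT and WAT at one temperature could share a mouse. Between them it ran from -0.238 to 0.0547 at 30 °C and from 0.0108 to 0.287 at 5 °C, which does not exclude pairing. Groups were treated as unpaired, with a replicate block as an alternative. In the fits of a single tissue the block joined equal numbers of different temperatures, which cannot share a mouse. There it does not test a shared mouse. In the fits of all 16 libraries it joined BAT and WAT of equal number at one temperature.

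Counts were scaled by TMM and filtered with filterByExpr (minimum count 10, minimum total 15), and group differences were tested by the edgeR quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3). BAT and WAT were fitted apart for the effect of temperature, which tested 16213 and 18975 genes. The difference between the temperature effects and the tissue differences at each temperature came from one fit of all 16 libraries and 19481 genes. Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05. SE is the absolute log2 fold change over the square root of F. CPM are scaled to the TMM-adjusted library size, given as mean ± SD with n = 4 unless stated.

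48 gene lists, 35 of pathways and functions and 13 of cell type markers, were tested by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, by camera with an estimated correlation, and by fry. Camera compares a list with the other genes. Fry asks whether the list's own genes move, on balance, one way. Of the 722 listed symbols, 719 matched directly, 2 through an older symbol and 1 not at all. Members past the threshold are counted over all genes tested and adjusted over the list alone.

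The lists, groups, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule names a panel of 22 genes in both tissues, up to 5 of the largest rises and 5 of the largest falls per comparison (at least 5 CPM in the higher group, groups not overlapping, no predicted genes), and up to 4 members with the smallest adjusted p of each list described. Members that did not pass may be named with their values, and 2 members that the rule names are not reported here. The same rule was also applied to the WAT comparison without WAT_5C replicate 1, a step added after the data were seen.

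The alternative settings fixed beforehand were RLE size factors, library totals without scaling, no filter, DESeq2 1.42.0 (Wald test), limma-voom with quality weights, an adjusted p of 0.01, each library left out in turn, all 16 libraries in one fit, and a replicate block. Added after the data were seen were the list counts under the scaling and left-out library settings, the list results without WAT_5C replicate 1, and the choice to single out that library among those left out.

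The pipeline was tested on simulated data made from the real libraries, with 200 genes changed. Far fewer genes changed there than in real BAT. Each gene was drawn independently, with a spread fitted over genes of like expression and without an outlying library. The shares called are therefore no estimate of power on the real data. In BAT, 35.8% of genes changed 1.5-fold, 62.7% of those changed 2-fold and 92.4% of those changed 4-fold were called, with 7 false calls. In WAT the shares were 4.48%, 26.9% and 74.2%, and without WAT_5C replicate 1 they were 19.4%, 53.7% and 95.5%. For the difference between the temperature effects they were 0%, 17.9% and 65.2%. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.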

Results

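RNA was measured in brown adipose tissue (BAT), the fat that burns fuel to make heat, and in inguinal white adipose tissue (WAT), a fat store under the skin, of female C57BL/6 wild-type mice. The mice were bred and weaned at 30 °C, near the temperature at which a mouse needs no extra heat, and were 16 weeks old at collection, after 2 to 3 h without food. The cold-housed mice were moved at 10 to 12 weeks of age to 18 °C for 2 weeks and then to 5 °C for 3 weeks, and the others stayed at 30 °C. The 16 libraries form 4 groups of 4, called BAT_30C, BAT_5C, WAT_30C and WAT_5C. Depth ran from 54264023 to 71289020 counts per library. The tissue label of the brown fat libraries names an inguinal depot. In 4 of the 8 BAT libraries, replicates 1 and 2 of BAT_5C and replicates 3 and 4 of BAT_30C, the source label gave the opposite temperature to the title and the housing label, which set the groups. Ucp1 was at 12388 CPM or more in every BAT_5C library and at 2019 CPM or less in every BAT_30C library.

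Transcripts of the mitochondrial genome took 24.2 to 26.8% of the counts in BAT_30C, 17.6 to 19.4% in BAT_5C, 3.19 to 4.18% in WAT_30C and 4.04 to 9.59% in WAT_5C. Fasn alone took 4.09 to 4.62% of the counts in BAT_5C against 0.162 to 0.381% in BAT_30C. Changes are therefore relative to TMM scaling. With library totals alone, the median log2 fold change of all genes moved by -0.38 in BAT, by -0.25 in WAT, by -0.85 between the tissues at 30 °C and by -0.93 at 5 °C.

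WAT_5C replicate 1 stood apart. It held 3 counts of Xist, the RNA made from the inactive X chromosome of females, against 11136 to 88934 in the other 15 libraries, and 17183 counts over 4 Y-linked genes against at most 45. The geometric mean of 14 mammary epithelium markers was 1.29 CPM in it and 43.2 to 59.9 CPM in the other 7 WAT libraries, and that of 15 T and NK cell markers was 7.81 CPM against 25.8 to 45.5 CPM. On the first principal component, which held 72.5% of the variance, it scored 13.9, between the other WAT libraries (126 to 163) and the BAT libraries (-165 to -106). Its Pearson correlation with the other WAT_5C libraries, across genes that are not independent replicates, was 0.908 to 0.936, while theirs was 0.984 to 0.989. Counts and list values that use WAT_5C, and the named genes that led with it or moved most, are therefore also given without it.

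**Figure D1:**
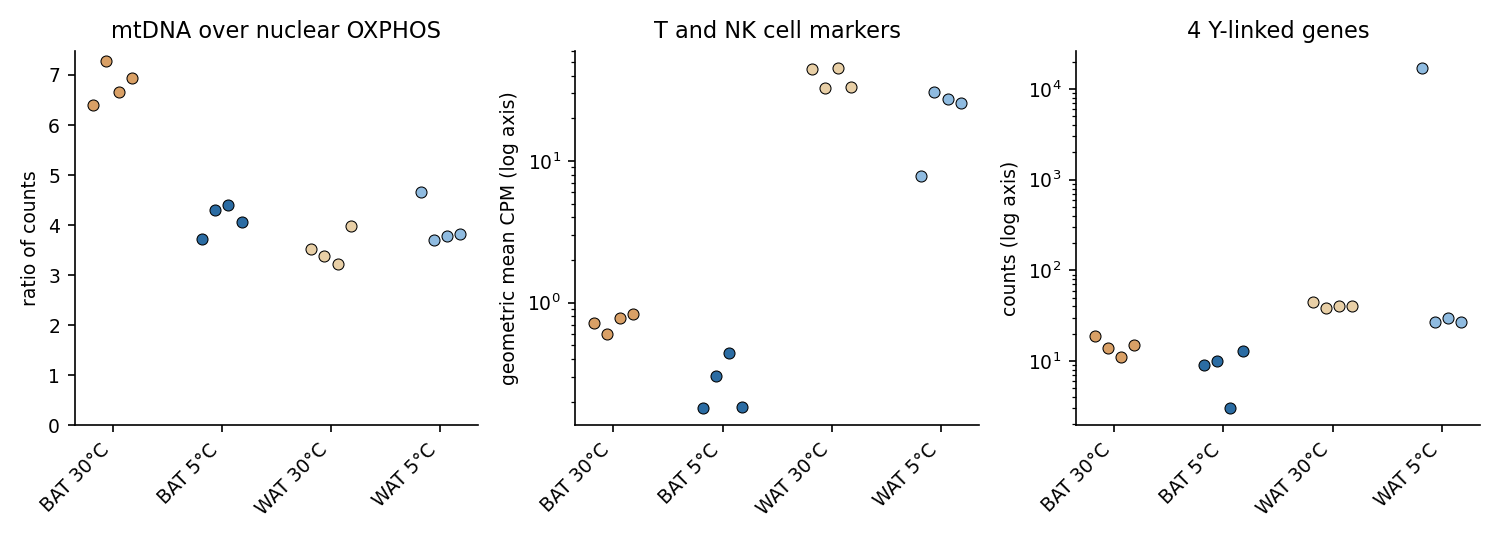
Per-library ratio of mitochondrially encoded to nuclear OXPHOS counts, geometric mean CPM of T and NK cell markers (log axis) and counts of 4 Y-linked genes (log axis), 1 point per library in the 4 groups. WAT_5C replicate 1 lies lowest among WAT libraries for T and NK cell markers (7.81 CPM) and highest for Y-linked counts (17183), and the ratio is lower in each BAT_5C library than in each BAT_30C library.

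The first comparison, BAT_5C against BAT_30C, asked how brown fat changed after weeks of cold. Ucp1 (ENSMUSG00000031710), the uncoupling protein that turns the mitochondrial proton gradient into heat, rose from 1326 ± 731 CPM (SD, n = 4) to 13046 ± 624 CPM. Elovl3 (ENSMUSG00000038754), an elongase of very long chain fatty acids, rose from 0.287 ± 0.29 to 803 ± 88 CPM. Fasn (ENSMUSG00000025153), which builds palmitate, rose from 2819 ± 1046 to 66156 ± 5484 CPM, and Acly (ENSMUSG00000020917), which supplies cytosolic acetyl-CoA, from 649 ± 110.2 to 11380.0 ± 1320.2 CPM. Lep (ENSMUSG00000059201), the satiety hormone of white fat, fell from 139.9 ± 58.6 to 18.1 ± 12.4 CPM. In log2 terms, with SE, Ucp1 changed by 3.30 ± 0.38 (SE, adjusted p = 4.99e-05), Elovl3 by 11.45 ± 0.52 (SE, adjusted p = 2.01e-07), Fasn by 4.56 ± 0.25 (SE, adjusted p = 5.71e-07), Acly by 4.13 ± 0.15 (SE, adjusted p = 5.40e-08) and Lep by -2.96 ± 0.58 (SE, adjusted p = 0.00167).

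Of the thermogenic list, 13 of 19 members rose and 0 fell, with the same count adjusted over the list alone. Its median log2 fold change was 0.79, and it ranked above other genes by camera (adjusted p = 0.000115, and adjusted p = 0.606 with an estimated correlation). Dio2, which makes active thyroid hormone, rose by 2.76 ± 0.63 (SE, adjusted p = 0.00409), and Acot11, an acyl-CoA thioesterase, by 5.34 ± 0.18 (SE, adjusted p = 4.57e-08). The lipid droplet protein gene Cidea rose by 0.79, Letmd1, of a mitochondrial inner membrane protein, by 1.85, and the cytochrome oxidase subunits Cox7a1 and Cox8b by 1.12 and 0.62. The glycerol kinase gene Gk rose by 3.07, the beta-3 adrenergic receptor gene Adrb3 by 1.01, and the hormone gene Fgf21 by 4.09 to 0.791 ± 0.18 CPM. The coactivator Ppargc1a had a log2 fold change of 0.56 (adjusted p = 0.18) and the carnitine transferase Cpt1b of 0.38 (adjusted p = 0.167), neither past the threshold. Slc27a2, a fatty acid transporter, was at 0.10 (adjusted p = 0.804) and the vascular growth factor Vegfa at 0.09 (adjusted p = 0.379). With library totals alone Slc27a2 turned to -0.27 and Vegfa to -0.29, the latter past the threshold, and without BAT_30C replicate 1 Slc27a2 turned to -0.13.

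Most listed genes of glucose uptake and glycolysis, of fatty acid synthesis and of cholesterol synthesis rose. In glucose uptake and glycolysis 18 of 21 members rose, with a list median of 1.52 (camera adjusted p = 5.19e-09, and adjusted p = 0.606 with an estimated correlation), among them Aldoa (2.80), Pfkl (3.22), Ldha (2.30), Eno1 (2.65) and the insulin-responsive glucose transporter Slc2a4 (1.24). In de novo lipogenesis, the making of fatty acids from sugar carbon, 16 of 18 rose and 2 fell, with a median of 2.34 (camera adjusted p = 5.01e-07, and adjusted p = 0.606 with an estimated correlation). The elongases Elovl6 and Elovl5 rose by 3.77 and 2.32, and the acetyl-CoA synthetase Acss2 by 2.69. In cholesterol synthesis 18 of 19 rose, with a median of 2.11 (camera adjusted p = 9.76e-08, and adjusted p = 0.606 with an estimated correlation), among them Pmvk (2.29), Insig1 (2.39), Idi1 (2.19) and Nsdhl (2.77). For these 3 lists the counts adjusted over the list alone were the same. Lpl, which frees fatty acids from blood lipids, rose by 0.86, and Angptl4, an inhibitor of that enzyme, fell by 1.65.

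**Figure D2:**
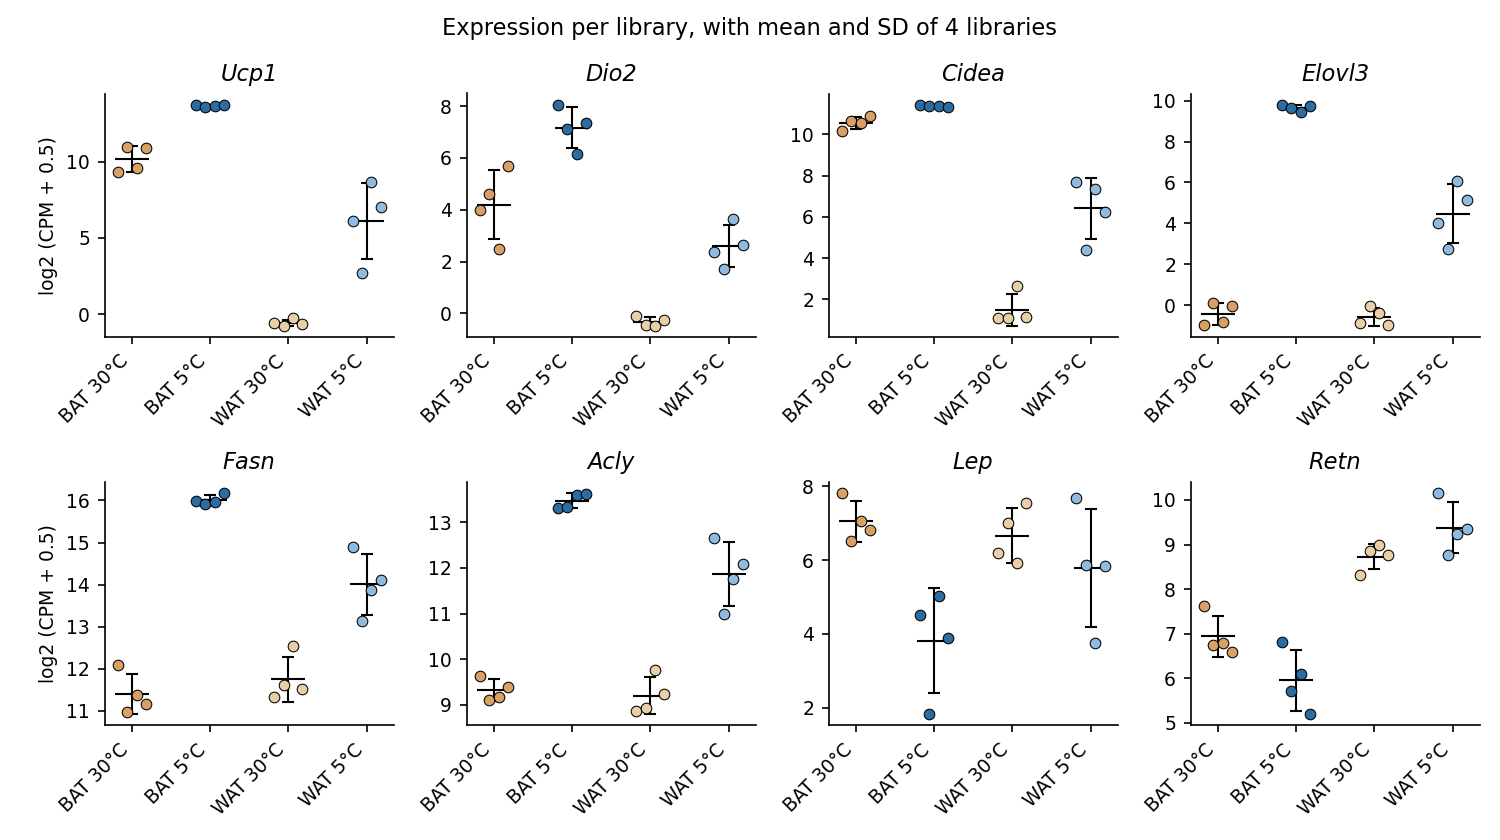
Log2 of CPM plus 0.5 of 8 panel genes, 1 point per library in the 4 groups, with the mean ± SD of each group. Ucp1, Dio2, Cidea, Elovl3, Fasn and Acly are higher on average in BAT_5C than in BAT_30C and Lep is lower there, while WAT_5C libraries spread widely for Ucp1 (150.1 ± 173 CPM).

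Genes of fuel oxidation rose as well. Of the TCA cycle list 18 of 18 members rose, with a median log2 fold change of 0.87 (camera adjusted p = 8.40e-08, and adjusted p = 0.606 with an estimated correlation), including the pyruvate dehydrogenase subunits Pdhb (1.86), Pdha1 (1.51) and Dlat (1.41). Of the fatty acid oxidation list 16 of 21 rose and 1 fell (median 0.79, camera adjusted p = 1.76e-05, and adjusted p = 0.606 with an estimated correlation). Acsl5, which activates long chain fatty acids, had the smallest adjusted p of any gene (5.07 ± 0.10 (SE, adjusted p = 1.23e-08)), and Hadha, Cpt2 and Decr1 rose by 1.84, 2.00 and 1.05. Pdk4, which restrains pyruvate oxidation, rose by 0.60 (adjusted p = 0.0221), but not past the threshold without BAT_5C replicate 2 (0.46, adjusted p = 0.0601). Subunits of the respiratory chain encoded in the nucleus rose in 29 of 36 for complex I (1 fell), 14 of 14 for complexes II and III, 11 of 13 for complex IV and 12 of 16 for complex V (2 fell). Under library totals, which lower the fold changes in BAT, 17 rose and 7 fell for complex I, 10 and 0 for complexes II and III, 6 and 2 for complex IV, 5 and 5 for complex V, 13 and 0 for the TCA cycle and 11 and 4 for fatty acid oxidation. Adjusted over the list alone, complex I had 30 rising and the other complexes had the same counts. Their medians ran from 0.45 to 0.70, and their camera adjusted p from 3.24e-07 to 0.00257 (adjusted p = 0.674 with an estimated correlation for complex I and 0.606 for the others). Uqcrc2 rose by 1.16, Uqcrfs1 by 1.06 and Sdha by 0.97.

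The 13 protein-coding genes of the mitochondrial genome moved apart, 3 rising and 4 falling with a median of -0.10 (camera adjusted p = 0.856), the same counts adjusted over the list alone, and 1 rising and 6 falling under library totals. mt-Nd1 rose by 0.73 and mt-Nd2 by 0.34, the latter turning to -0.04 with library totals alone, while mt-Co1 fell by 0.50 and mt-Co3 by 2.72. Of the 50-base windows of mt-Co3 99.9% occur in other annotated transcripts, and of those of mt-Co1 51.1%. The counts of both can hold or lose shared reads. For mt-Nd1 and mt-Nd2 the shares are 0 and 8.19%. In BAT_30C the summed count of the 13 genes over that of 79 nuclear OXPHOS genes was 6.82 ± 0.38 (SD, n = 4). This ratio was 4.12 ± 0.305 in BAT_5C (exact permutation test, two-sided p = 0.0286, the smallest the design allows). In WAT the ratio was 3.53 ± 0.328 at 30 °C and 3.99 ± 0.447 at 5 °C (exact permutation test, two-sided p = 0.143), with WAT_5C replicate 1 at 4.66 and the other WAT_5C libraries at 3.70 to 3.83.

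Among genes that fell, 7 of 11 markers of white fat passed and 1 rose, with a median of -1.20, the same counts adjusted over the list alone, and a camera adjusted p of 0.123. Nnat fell by 7.54, Sncg by 1.65, the nuclear corepressor gene Nrip1 by 1.47 and the adipocyte hormone gene Retn by 0.93 (adjusted p = 0.0374). Retn missed the threshold without any 1 of 6 libraries, with an adjusted p of up to 0.114 and a fall of 0.63 without BAT_30C replicate 1. Of the T and NK cell markers 9 of 15 fell, with a median of -1.46 (camera adjusted p = 0.00655, and adjusted p = 0.606 with an estimated correlation), and their geometric mean was 0.599 to 0.828 CPM in BAT_30C and 0.179 to 0.439 CPM in BAT_5C. Cd3g fell by 2.40, Cd4 by 1.46, Lck by 1.72 and Nkg7 by 2.06. No other cell type list passed camera in BAT. Skeletal muscle markers varied from 0.283 to 142 CPM between BAT libraries of either temperature, and 1 of 13 rose.

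The largest rises by the naming rule, beside Elovl3, were of the Wnt agonist gene Rspo4, with 1 count in BAT_30C and a ratio of 3848 (95% counting interval 690.1 to 152021), Ptprn2 (7.72, and 8.92 without BAT_30C replicate 1), Atp4b, of the gastric proton pump (7.68), and the cytochrome P450 gene Cyp1a1 (7.50). The largest falls were of Shisa7, at 0 counts in BAT_5C and at least 325-fold lower there, Akr1cl (-8.90, and -13.03 without BAT_5C replicate 1), Cdhr5 (-8.72), Prr32 (-7.76) and Nnat. By the edgeR test, 9647 of 16213 genes changed, 4741 rising and 4906 falling, and 3121 of them by 2-fold or more. Camera passed 19 of 48 lists with the preset correlation and 0 with an estimated one, fry passed 27, and 42 passed for change in either direction. With library totals alone 2323 genes rose and 8831 fell, and the 4 libraries whose labels all match gave 6058 changed genes. Grouping by the conflicting source label gave 0 genes.

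The comparison of WAT_5C with WAT_30C asked whether inguinal white fat took on features of brown fat in the cold. Ucp1 was at 0.179 ± 0.102 CPM (SD, n = 4) at 30 °C and at 150.1 ± 173 CPM at 5 °C, a log2 fold change of 9.67 ± 1.40 (SE, adjusted p = 0.0639) that missed the threshold. Dio2 rose from 0.305 ± 0.0923 to 6.32 ± 4 CPM, by 4.33 ± 0.50 (SE, adjusted p = 0.0407). Agpat2, which makes phosphatidic acid on the way to triglyceride, rose by 2.60 ± 0.32 (SE, adjusted p = 0.0465), and the fatty acid desaturase Fads2 by 1.04 ± 0.12 (SE, adjusted p = 0.0407). The urinary protein gene Mup3 rose by 3.83 ± 0.35 (SE, adjusted p = 0.0305), the copper-binding oxidase gene Hephl1 by 3.50 ± 0.36 (SE, adjusted p = 0.0319) and AA914427 by 2.67 ± 0.31 (SE, adjusted p = 0.0407). Without WAT_5C replicate 1, 1 of the left-out settings fixed beforehand but singled out after the data were seen, Ucp1 rose by 9.92 ± 1.40 (SE, adjusted p = 0.0208), Elovl3 by 7.43 ± 1.03 (SE, adjusted p = 0.0201) and Cidea by 4.96 ± 0.76 (SE, adjusted p = 0.0246).

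Of the thermogenic list, 1 of 19 members passed over all genes and 15 adjusted over the list alone, all rising. Its median log2 fold change was 2.50 (camera adjusted p = 3.67e-14, and adjusted p = 0.519 with an estimated correlation). Without WAT_5C replicate 1, 9 passed over all genes and 15 adjusted over the list alone, with a median of 2.30. Otop1, of a proton channel, then rose by 4.94, Cox8b by 2.49, Slc27a2 by 5.67 and Dio2 by 4.44. With all 8 libraries Cidea was at 5.40 (adjusted p = 0.0704), Elovl3 at 7.22 (adjusted p = 0.072), Cox8b at 3.06 (adjusted p = 0.096) and Slc27a2 at 5.61 (adjusted p = 0.0745). The lists of beige and of white fat markers did not move with the thermogenic list. Their medians with all 8 libraries were 0.003 and 0.05, and -0.32 and -0.25 under library totals.

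In de novo lipogenesis 1 of 18 members passed over all genes and 15 adjusted over the list alone, all rising, with a median of 2.17 (camera adjusted p = 8.81e-17, and adjusted p = 0.519 with an estimated correlation). Without WAT_5C replicate 1 the counts were 14 and 15, and Acly rose by 2.40, Acacb, which makes malonyl-CoA, by 2.59, the desaturase Scd2 by 1.18, Thrsp by 1.83, Fasn by 1.90 and Elovl6 by 2.88. In fatty acid oxidation 0 of 21 passed edgeR over all genes and 19 adjusted over the list alone, with a median of 1.53 (camera adjusted p = 4.62e-13, and adjusted p = 0.519 with an estimated correlation). Without that library 10 and 20 rose, among them Slc25a20 (1.54), Acadl (1.34), Hadhb (1.55) and Hadha (1.34). In the TCA cycle the counts were 0 and 18 of 18 with all libraries and 5 and 18 without it, when Dlat rose by 1.71, Pdhb by 1.51 and Idh3a by 1.36. In cholesterol synthesis they were 0 over all genes and 12 rising and 2 falling adjusted over the list alone, and 5 over all genes without it, Lss rising by 1.28 and Pmvk by 1.30. Complex I subunits had a median of 0.82, 0 of 36 past the threshold over all genes and 29 adjusted over the list alone, and the mitochondrially encoded genes a median of 1.196, 0 and 8 of 13. With that library left out these medians were 0.50 and 0.66. Camera ranked the TCA cycle and cholesterol synthesis as well as these 2 lists above other genes (adjusted p from 4.45e-14 to 1.45e-05, each with adjusted p = 0.519 with an estimated correlation).

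**Figure D3:**
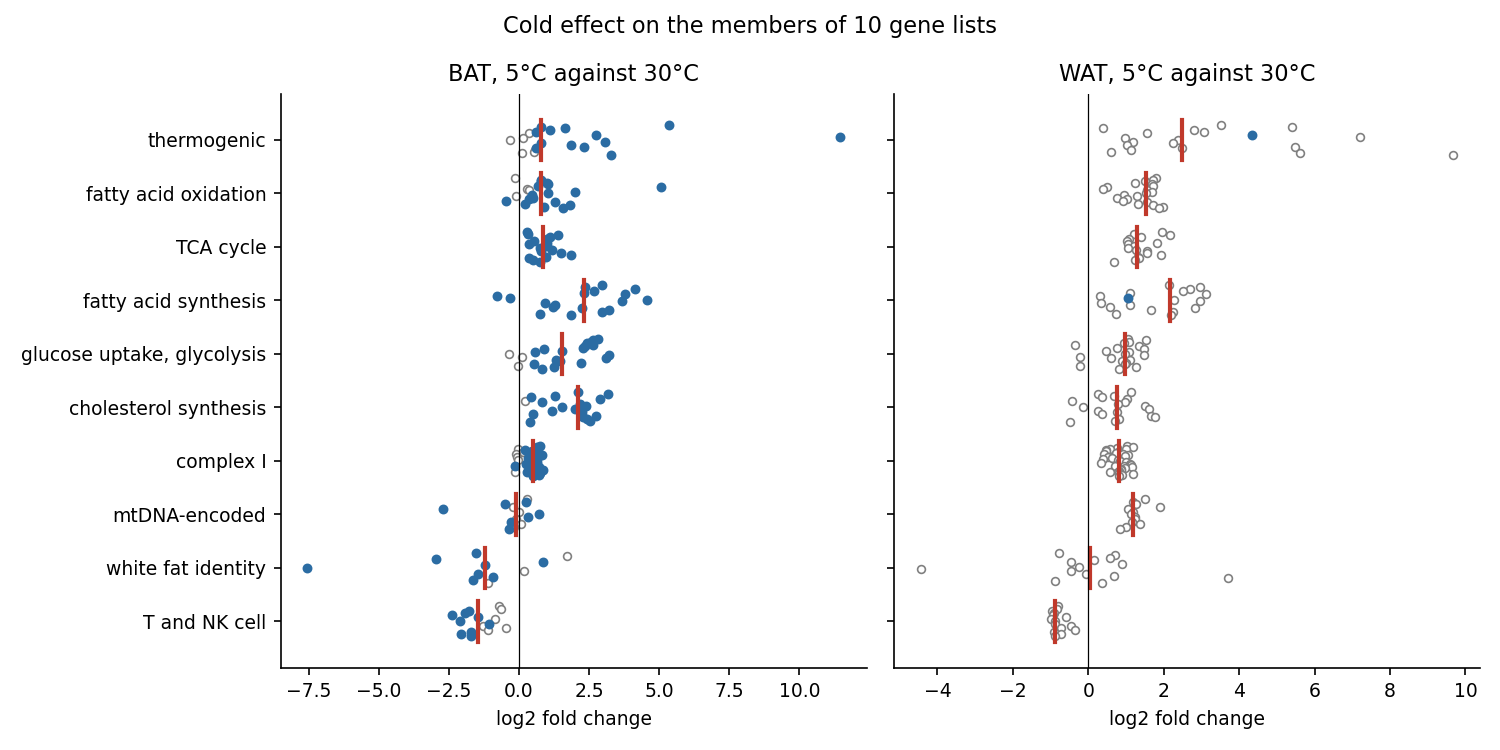
Log2 fold change at 5 °C over 30 °C of the tested members of 10 gene lists in BAT and in WAT (all 8 libraries each), 1 point per gene, filled where the adjusted p over all genes is under 0.05, with a red line at the list median. In BAT 18 of 18 TCA cycle genes are filled and in WAT 0, although the WAT median of 1.29 is above the BAT median of 0.87.

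In WAT no T and NK cell or skeletal muscle marker passed the threshold in edgeR with all 8 libraries. T and NK cell markers had a median of -0.87 (camera adjusted p = 2.05e-05, and adjusted p = 0.519 with an estimated correlation), with 0 of 15 past the threshold. Leaving out WAT_5C replicate 1, the median was -0.57 and 11 fell adjusted over the list alone, 0 over all genes, Cd3g standing at -0.63 (adjusted p = 0.0587). Skeletal muscle markers had a median of -1.07 (camera adjusted p = 0.0163, and adjusted p = 0.694 with an estimated correlation), and their geometric mean ran from 6.28 to 174 CPM in WAT_30C and from 0.677 to 147 CPM in WAT_5C, the highest in replicate 1, so the groups overlapped. The largest falls by the naming rule without replicate 1 were of Nnat (-5.39), Hspd1-ps4 (-1.83), the secretin receptor gene Sctr (-1.58), the lactoferrin gene Ltf (-1.45) and Phgdh (-1.13), the entry enzyme of serine synthesis.

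Of the rest of the panel, each value is given with all 8 WAT libraries and then without WAT_5C replicate 1. Acly was at 2.71 (adjusted p = 0.0691) and 2.40, Elovl6 at 3.13 (adjusted p = 0.0707) and 2.88, Fasn at 2.28 (adjusted p = 0.131) and 1.90, and Pdk4 at 2.50 (adjusted p = 0.131) and 2.03. Cox7a1 was at 2.80 and 2.30, Gk at 1.18 and 1.004, Slc2a4 at 1.26 and 0.81, Lpl at 0.90 and 0.14, Ppargc1a at 1.13 and 0.66, Angptl4 at 0.46 and 0.23, Vegfa at 0.48 and 0.16, and Cpt1b at 1.57 and 1.37, none past the threshold either way. Retn was at 0.69 (adjusted p = 0.276) and 0.35, Lep at -0.45 (adjusted p = 0.744) and -1.42 (adjusted p = 0.189), and Adrb3 at 0.29 (adjusted p = 0.737) and -0.34, the last turning to -0.09 with library totals alone. Fgf21, at 0.169 ± 0.0994 CPM in WAT_5C, was too low to test.

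By the edgeR test 12 of 18975 genes changed in WAT, all rising, 11 of them by 2-fold or more, and 3430 had an unadjusted p under 0.05. DESeq2 called 1119 and limma-voom with quality weights 2268. Without WAT_5C replicate 1 edgeR called 408 of 19320, 355 rising and 53 falling, and all 12 were among them. Each of the 6 risers named above missed the threshold without any 1 of 6 libraries. Without WAT_5C replicate 2 edgeR called 273, without WAT_30C replicate 1 it called 1, and without any other library 0. With the replicate block, which here joined libraries of different temperatures, it called 0. Library totals gave 82 (73 rising and 9 falling) and all 16 libraries in one fit 1587.

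Among genes tested in both tissues, 236 of the 313 that rose in WAT without replicate 1 also rose in BAT, against 91.5 expected if the calls were independent, and 30 of the 41 that fell also fell in BAT, against 12.4. The log2 fold changes of the 2 tissues had a Pearson correlation of 0.298 and a Spearman correlation of 0.386 across genes, which are not independent replicates.

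**Figure D4:**
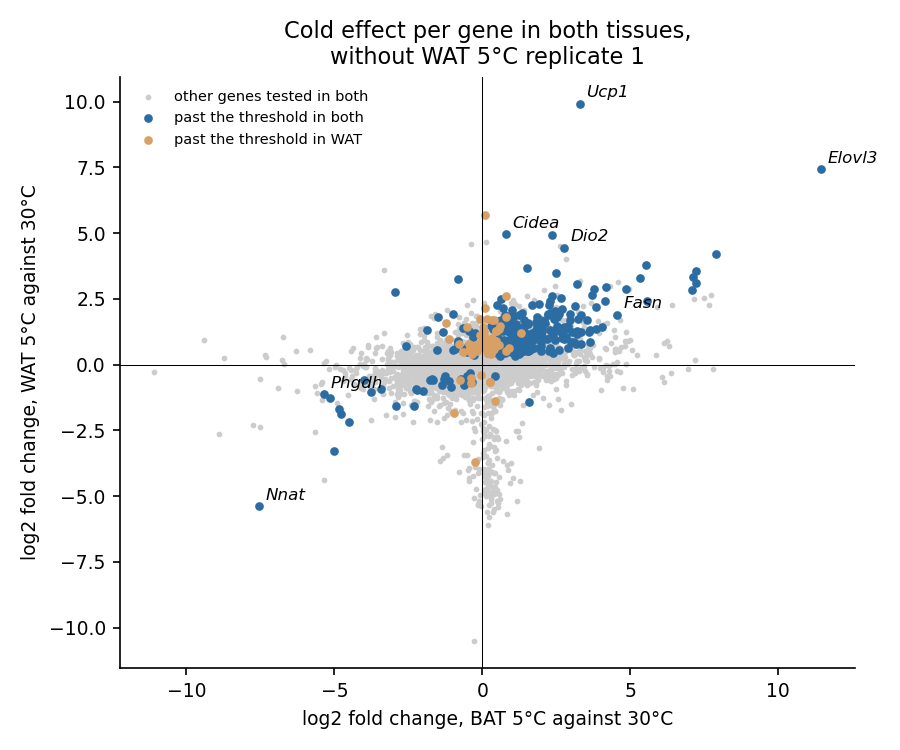
Log2 fold change at 5 °C over 30 °C in BAT (x axis) and in WAT without WAT_5C replicate 1 (y axis), 1 point per gene tested in both. Of the 313 genes that rose in WAT, 236 also rose in BAT and 20 fell there.

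Whether the effect of cold differed between the tissues was tested as its own contrast, the WAT effect minus the BAT effect. Ucp1 differed by 6.41 ± 1.23 (SE, adjusted p = 0.00198), Cidea by 4.64 ± 0.79 (SE, adjusted p = 0.000893) and Slc27a2 by 5.54 ± 0.98 (SE, adjusted p = 0.00119), each with the larger log2 fold change in WAT, where their levels at 30 °C were far lower. The Ucp1 call ended with limma-voom (adjusted p = 0.128), its adjusted p running from 0.000107 to 0.128 over all alternatives, while those of Cidea and Slc27a2 reached 0.00581 and 0.0362. Without WAT_5C replicate 3 Ucp1 differed by 5.25 and Slc27a2 by 4.63, and without WAT_5C replicate 1 Ucp1, Cidea and Slc27a2 differed by 6.61, 4.16 and 5.55, Hk1, Pfkp and Fasn by -2.79, -2.74 and -2.67 and Phgdh by 4.21. The glycolytic enzymes Hk1 (-2.94 ± 0.25 (SE, adjusted p = 3.66e-06)) and Pfkp (-2.46 ± 0.23 (SE, adjusted p = 8.63e-06)) and the lipogenic gene Fasn (-2.24 ± 0.55 (SE, adjusted p = 0.00925)) had the larger log2 fold change in BAT. The serine synthesis gene Phgdh differed by 4.69 ± 0.51 (SE, adjusted p = 2.92e-05), having fallen by 5.35 in BAT. Dio2, at 1.61 (adjusted p = 0.218), was not shown to differ.

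Cholesterol synthesis genes had lower fold changes in WAT than in BAT, with 12 of 19 members over all genes, 14 adjusted over the list alone and a median difference of -0.90 (camera adjusted p = 6.51e-07, and adjusted p = 0.892 with an estimated correlation), including Sqle (-1.80), Sc5d (-1.58) and Idi1 (-1.36). The glucose uptake and glycolysis list did so in 10 of 21 and the reverse in 1, with the same counts adjusted over the list alone. Its median was -0.998 (camera adjusted p = 0.00036, and adjusted p = 0.892 with an estimated correlation), with Gpi1 at -1.43 and Pdk1 at -1.02. The mitochondrially encoded genes lay the other way, with a median of 1.24 (camera adjusted p = 0.0464, and adjusted p = 0.892 with an estimated correlation), 2 of 13 past the threshold over all genes and 9 adjusted over the list alone, and 8 over all genes under library totals. Without WAT_5C replicate 1 their median difference was 0.65, with 5 and 5 past the threshold, and those of cholesterol synthesis and glycolysis were -1.21 and -1.38. Of the thermogenic list 7 members had the higher fold change in WAT and 3 in BAT (9 and 4 adjusted over the list alone, camera adjusted p = 0.313). Among the latter were Gk (-1.85) and Elovl3 (-4.20, adjusted p = 0.0271), which missed the threshold without any 1 of 3 libraries, with an adjusted p of up to 0.129, and over all alternatives from 0.0121 to 0.302.

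By the edgeR test the cold effect differed in 4055 of 19481 genes, 2431 higher in WAT and 1624 higher in BAT. The split moved with the scaling, to 2056 and 2099 with RLE size factors and to 2608 and 1080 with library totals. There were, without WAT_5C replicate 1, 6222, 3101 higher in WAT and 3121 higher in BAT, and limma-voom gave 6797.

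BAT_30C against WAT_30C asked how the depots differ without cold. Ucp1 was higher in BAT by 12.85 ± 1.25 (SE, adjusted p = 4.59e-07), Slc27a2 by 11.65 ± 0.91 (SE, adjusted p = 6.02e-08) and Cidea by 9.16 ± 0.76 (SE, adjusted p = 1.03e-07). Zic1, a transcription factor used as a brown fat marker, was higher in BAT by 7.20 ± 0.55 (SE, adjusted p = 4.66e-08), and Hoxc9, a homeobox gene used as a white fat marker, was lower (-7.13). Glycam1, a mucin of lymph node vessels and mammary gland, had 3 counts in BAT_30C and a ratio of WAT to BAT of 37355 (95% counting interval 12782 to 181137). Csn3, a milk casein, was lower in BAT (-9.82, and -14.10 without BAT_30C replicate 2), as was the B cell gene Ms4a1 (-7.66).

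Of the thermogenic list 17 of 19 members were higher in BAT and 1 lower, with a median log2 difference of 5.97 (camera adjusted p = 2.18e-07, and adjusted p = 0.393 with an estimated correlation), among them Cox8b (6.05), Esrrg (4.15) and Letmd1 (3.49). All 36 complex I subunits tested were higher in BAT, with a median of 2.68 (camera adjusted p = 2.12e-15, and adjusted p = 0.393 with an estimated correlation), as were all 13 mitochondrially encoded genes (median 3.65, camera adjusted p = 2.82e-06, and adjusted p = 0.393 with an estimated correlation) and 19 of 21 fatty acid oxidation genes, Acaa2 by 5.58 and Acadl by 4.13. Of the brown identity list 11 of 13 were higher in BAT, Ntrk3 by 4.25, and 1 was lower, Epsti1 by 5.19 (camera adjusted p = 0.000255, and adjusted p = 0.393 with an estimated correlation). Of the beige list 8 of 11 were lower in BAT, Tmem26 by 6.12, and 2 higher (camera adjusted p = 0.0339, and adjusted p = 0.393 with an estimated correlation). For the 5 lists the counts adjusted over the list alone were the same.

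Lymphoid, mammary and macrophage markers were lower in BAT and endothelial markers higher. All 12 B cell markers (median -7.63), all 15 T and NK cell markers (median -6.22), all 14 mammary markers (median -7.37) and 14 of 15 macrophage markers (median -1.88) were lower in BAT, with camera adjusted p from 6.71e-08 to 0.000301 (adjusted p = 0.393 to 0.399 with an estimated correlation). Cd79a was lower by 6.36, Prlr by 5.96 and C1qc by 1.93. All 10 endothelial markers were higher in BAT (median 1.46, camera adjusted p = 0.000126, and adjusted p = 0.393 with an estimated correlation), Tie1 by 2.08 and Kdr by 2.02, with 8 higher and 1 lower under library totals. The same members passed in number when adjusted over the list alone. Among the largest differences, Magel2 was at 0 counts in WAT_30C and at least 867-fold higher in BAT_30C, and Sgk2 was higher in BAT by 9.70. Dsc3, Aoc1, Hoxc10 and Sprr1a were at 0 counts in BAT_30C and at least 2153-, 1978-, 547- and 528-fold lower there. By the edgeR test 13596 of 19481 genes differed, 6712 higher in BAT and 6884 lower, and with library totals alone 2505 were higher and 12875 lower.

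BAT_5C against WAT_5C asked how the depots differ after cold. Ucp1 was higher in BAT by 6.44 ± 0.95 (SE, adjusted p = 2.49e-05) and Cidea by 4.52 ± 0.62 (SE, adjusted p = 1.13e-05), and the secreted factor gene Bmp8b by 9.28 ± 0.86 (SE, adjusted p = 2.53e-07). The guanosine monophosphate reductase gene Gmpr was higher by 6.80 ± 0.51 (SE, adjusted p = 3.61e-08), Kng2, of a kininogen, by 7.03 ± 0.44 (SE, adjusted p = 1.05e-08) and Rspo4 by 7.90 ± 0.50 (SE, adjusted p = 1.09e-08). Glycam1 (-13.79) and Retn (-3.40) were lower in BAT. With WAT_5C replicate 1 left out the differences were 6.18 for Ucp1, 4.94 for Cidea, 9.06 for Bmp8b, 7.21 for Gmpr, 7.02 for Kng2, 7.83 for Rspo4, -14.21 for Glycam1 and -3.08 for Retn, and that of Ucp1 was 7.60 without WAT_5C replicate 3. Dsc3, Hoxc10, Il22ra2 and Ighg1 were at 0 counts in BAT_5C and at least 981-, 688-, 659- and 419-fold lower there.

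Genes of the glucose uptake and glycolysis list were higher in BAT in 18 of 21 cases and lower in 1. The median was 2.63 (camera adjusted p = 1.31e-07, and adjusted p = 0.334 with an estimated correlation). Among those higher were Pfkl (3.77), Gpi1 (2.93), Hk1 (2.63) and Pfkp (2.57). In cholesterol synthesis 17 of 19 were higher in BAT at 5 °C (median 0.94, camera adjusted p = 0.000193, and adjusted p = 0.334 with an estimated correlation), while at 30 °C 5 were higher and 5 lower (4 and 5 adjusted over the list alone). Under library totals 5 cholesterol synthesis genes were higher in BAT and 3 lower at 5 °C, and 2 higher and 16 lower at 30 °C. Hmgcs1 was higher in BAT_5C by 1.81, Insig1 by 1.72 and Fdft1 by 1.23. The thermogenic list was higher in 18 of 19 and lower in 1 (median 4.48, camera adjusted p = 2.27e-07, and adjusted p = 0.334 with an estimated correlation). White fat markers were lower in BAT in 11 of 14 (camera adjusted p = 0.0225, and adjusted p = 0.441 with an estimated correlation), Hoxc9 by 6.25, Sncg by 2.72 and Nrip1 by 2.08. Extracellular matrix genes were lower in 18 of 23 and higher in 2 (camera adjusted p = 0.000856, and adjusted p = 0.334 with an estimated correlation), Mmp2 by 2.87, Col1a2 by 2.25 and Col3a1 by 2.21. These 5 lists had the same counts at 5 °C adjusted over the list alone. When WAT_5C replicate 1 was left out, the medians were 2.92 for glycolysis, 1.13 for cholesterol synthesis, 4.59 for the thermogenic list, -1.88 for white fat markers, which camera then did not pass (adjusted p = 0.112), and -1.63 for extracellular matrix, and Sncg stood at -1.86. By the edgeR test 14098 of 19481 genes differed, 6201 higher in BAT and 7897 lower, and 15125 without WAT_5C replicate 1, with 2118 higher and 13882 lower under library totals.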

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

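Chosen only after the results were seen were the tests of mixed male RNA and of a swap, the test of carried brown fat, the tests of shared reads and of a few abundant genes, and the splits with the BAT groups kept. Leaving out each library in turn was fixed beforehand, but the choice to single out WAT_5C replicate 1 was made after its counts were seen. Of 308 groups of 4 libraries examined, 21 (6.82%) held a library whose gap to its nearest neighbour, divided by the group's range, was beyond Dixon's critical value, where chance gives about 1 in 20.

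WAT_5C replicate 1 lay far from the rest of its group in Y-linked counts (17183 against at most 45, gap over range 0.9998), mammary epithelium markers (0.987), mesothelium and keratinocyte markers (0.958) and T and NK cell markers (0.871), 4 of the 21. Male RNA mixed into a female sample is argued against by Xist, at 0.0175% of the lowest level among the other 15 libraries, and a swap with a library of another group by the lack of a partner: 0 of the 12 libraries of the other 3 groups lay with the WAT_5C libraries, Ucp1 being at most 0.324 CPM in WAT_30C against at least 6.08 CPM in the other WAT_5C libraries, and the first principal component at most -106 in BAT against at least 126 in the other WAT libraries. The 3 Xist counts, against at least 11136 in the other 15 libraries, and the Y-linked counts argue against a female mouse as the source. A further test of a male mouse did not decide. In it, 4 X-linked genes that escape inactivation had a median log2 ratio of -0.25 to the other WAT libraries. The ratio was outside the -0.07 to 0.05 of those libraries but short of the bound of -0.3 set beforehand. Kdm6a stood at -1.04 and Ddx3x at -0.10. A sample from outside the series may also account for the library and was not tested. The labels name females only, and beyond the sex of the mouse no biological explanation was tested.

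The thermogenic list had a median of 2.50 in WAT_5C against WAT_30C and ranked above other genes by camera (adjusted p = 3.67e-14) but not with an estimated correlation (adjusted p = 0.519), with 1 of 19 members past the threshold over all genes and 15 adjusted over the list alone. A first test of carried brown fat did not argue against it. It used 9 genes outside the list with at least 100 CPM in BAT_5C and at most 1% of that in WAT_30C. With the share set by Ucp1, 1.15%, the quartiles of their observed over predicted gain, 0.559 and 4.61 (median 2.84), include 1. The highest of the 9, at 17.6, was the predicted gene Gm10925. A bound added after that test argues against carried brown fat as the whole source, by 2 of the 9. Gmpr and Bmp8b gained 0.0638 and -0.113 of what was predicted. No WAT_5C library held more than 9.27 and 0.344 CPM of them, against 11.4 and 1.71 predicted. A rise in 1 library alone is argued against, since 73.7% of the 19 members tested (14) had the other 3 WAT_5C libraries above every WAT_30C library. For a single member chance gives 2.86%. The members were measured in the same libraries and are not independent, so 73.7% against 2.86% is no test. A carried part stays open. In replicate 3, where the share was 3.05%, the median was 1.05, but the quartiles were 0.0191 and 1.55. Part of the 9 genes thus fell far short of the predicted gain there, Gmpr and Bmp8b among them. A response of the white fat's own cells may account for the rest, a hypothesis found and tested on the same libraries.

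In BAT_5C the mitochondrially encoded transcripts did not follow the nuclear OXPHOS genes, with medians of -0.10 and 0.50. A few abundant genes such as Fasn dilute both sets alike and leave the ratio of their summed counts as it was, and that ratio, 1.65 times higher in BAT_30C (lowest library 6.40) than in BAT_5C (highest library 4.41), restates the pattern and is no separate test. Reads shared with other annotated transcripts are argued against as the whole cause by the 6 genes with few shared windows. Their ratio was 1.34 times higher in BAT_30C (3.23 ± 0.163 against 2.41 ± 0.163, SD, n = 4, exact permutation test, two-sided p = 0.0286). The bound it passed was added after the first test. Nuclear copies outside annotated transcripts were not searched, so reads shared with those stay open. An earlier test on the fold changes of the 6 genes decided nothing. Their upper quartile, 0.31, lay between the lower quartile and the median of the nuclear genes, 0.28 and 0.50. Their median was 0.11, while that of the 7 mitochondrial genes with more shared windows was -0.22. A lower share of mitochondrially encoded RNA in cold brown fat may be biological, a hypothesis from the same data, and a difference in how well poly(A) selection captured these transcripts was not tested.

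The effect of cold differed between the tissues, by the test of the difference itself, for 28 of the genes named, with adjusted p from 3.66e-06 to 0.0364. List members were named because they passed, so 28 is no measure of how often genes differed. Of the 22 panel genes, fixed beforehand, 11 differed. Without WAT_5C replicate 1 it was 12, with Adrb3 (-1.35) and Lpl (-0.73) added and Pdk4 lost. Without any 1 library 7 of the 28 missed the threshold at least once, and 9 did under any alternative. In log2, WAT minus BAT, the thermogenic genes Ucp1, Cidea, Cox8b, Slc27a2 and Pdk4 stood at 6.41, 4.64, 2.48, 5.54 and 1.93, and Elovl3 and Gk at -4.20 and -1.85. Of the lipid genes, Fasn, Acly and Elovl5 stood at -2.24, -1.39 and -1.18, and Fads1, Fads2 and Angptl4 at 1.12, 1.38 and 2.13. Of the glucose uptake and glycolysis list, Hk1, Pfkp, Gpi1 and Pdk1 stood at -2.94, -2.46, -1.43 and -1.02. Of cholesterol synthesis, Sqle, Sc5d and Idi1 stood at -1.80, -1.58 and -1.36. Of serine and one-carbon metabolism, Phgdh, Aldh1l2, Psat1 and Shmt1 stood at 4.69, 2.81, 1.71 and 1.06, and Psph at -0.67. The hormone gene Retn stood at 1.65, and the mitochondrial genes mt-Co1 and mt-Nd4 at 1.80 and 1.45. Other annotated transcripts held 51.1 and 62.2% of the 50-base windows of mt-Co1 and mt-Nd4. The 7 were Elovl3, Acly, Pdk4, Retn, Psph, mt-Co1 and mt-Nd4, whose adjusted p reached 0.129, 0.0684, 0.0713, 0.0596, 0.0665, 0.0579 and 0.0748 without 1 library, and the other 2 were Ucp1 with limma-voom (0.128) and Psat1 at a threshold of 0.01 (0.0116).

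The other libraries far from their group, with the gap over the range, were these. In BAT_30C, replicate 3 was highest for complex V genes (0.831), replicate 1 lowest for adipogenic transcription factors (0.840) and replicate 2 highest for mammary epithelium markers (0.915). In BAT_5C, replicate 3 was lowest for Ppargc1a (0.857), Adrb3 (0.842), Vegfa (0.880) and lysosome and autophagy genes (0.933). Replicate 4 of BAT_5C was lowest for complex IV genes (0.869), and replicate 1 was highest for lipid uptake genes (0.847) and lowest in total counts (0.896). In WAT_30C, replicate 1 was lowest for Ppargc1a (0.935), creatine cycle genes (0.832), triglyceride synthesis genes (0.859) and lipid uptake genes (0.841). Replicate 3 of WAT_30C was highest for Cidea (0.972) and Elovl6 (0.896), and replicate 2 for mesothelium and keratinocyte markers (0.973).

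Other splits of the same libraries bear on the counts of genes. In BAT, 1 of 35 splits, the real one with 9647 genes, was as large and the next highest gave 0. This argues against chance, with 1 of 35 as the smallest share these splits can give. In WAT, 2 of 35 splits gave at least the real 12 genes and the highest other gave 121, so chance cannot be excluded, and that split exchanged WAT_5C replicate 1 with WAT_30C replicate 1, which points to the structure that this library makes. With WAT_5C replicate 1 left out, 1 of 35 splits gave the real 408 and the highest other gave 130. That share is again the smallest possible. The library was singled out after its counts were seen, so chance is argued against only for that choice of libraries. For the difference of cold effects, 4 of 100 drawn splits reached the real 4055, with 8385 as the highest other, but each of the 4 kept the BAT libraries in their real groups, so this share rests on the BAT effect. With the BAT groups kept, 51 of the 70 ways to label the WAT libraries reached 4055 and the highest other gave 8552, with a median of 4799 over the others. The kept BAT effect alone gives counts of this size, so that count cannot decide on the grouping of WAT. Between the tissues, 1 of 35 splits reached the real value at 30 °C (13596, highest other 0) and 1 of 35 at 5 °C (14098, highest other 5845, an exchange of WAT_5C replicate 1 with BAT_5C replicate 2). Chance is argued against for both, at the same smallest share.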

How the results depend on the processing

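None of these values shows a cause beyond what an alternative changes by its construction, so where a call or count moved the cause was not tested. The list counts under other scalings and with left-out libraries were chosen after the data were seen, while leaving out each library for the gene counts and named genes was fixed beforehand. The counts of genes that differed between the tissues at 30 °C and at 5 °C stayed within 1.5 times their value under every alternative run, from 12916 to 14443 and from 13428 to 15125 with 1 library left out.

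For BAT, with 9647 genes changed, the groups of the source label gave 0 and the 4 libraries whose labels all match gave 6058, a test of fewer samples, while 1 library left out gave 8742 to 9295. For WAT, with 12, library totals gave 82, no filter 25, DESeq2 1119, limma-voom 2268 and all 16 libraries in one fit 1587, an adjusted p under 0.01 gave 0, and the replicate block gave 0. The range with 1 library left out was 0 to 408, the highest without WAT_5C replicate 1, then 273 without WAT_5C replicate 2, 1 without WAT_30C replicate 1 and 0 without WAT_30C replicates 2, 3 or 4 or WAT_5C replicates 3 or 4. For the difference of cold effects, with 4055, limma-voom gave 6797, an adjusted p under 0.01 gave 2109, the replicate block 3384, and 1 library left out 3221 to 6222, the highest without WAT_5C replicate 1 and at most 4098 otherwise. With the replicate block, BAT gave 9091, and the tissue differences gave 13239 at 30 °C and 13811 at 5 °C. In the fits of BAT alone and WAT alone this block joined different mice, so those counts do not bear on pairing.

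Camera with an estimated correlation passed 0 lists in each of the 5 comparisons, against 19 in BAT, 28 in WAT, 3 for the difference of cold effects, 33 between the tissues at 30 °C and 38 at 5 °C with the preset one. Fry passed 27, 2, 2, 43 and 42. For the difference of cold effects RLE size factors passed 6 lists, library totals 7, and 1 library left out 2 to 12, the highest without WAT_5C replicate 2, then 11 without WAT_5C replicate 1 and 5 without BAT_5C replicate 3. With 1 library left out the other comparisons passed 18 to 19 in BAT, 25 to 30 in WAT, 32 to 35 at 30 °C and 37 to 39 at 5 °C.

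Of 223 results of named genes, 175 past the threshold, 4320 alternative values were computed, of which 4015 kept direction and side of the threshold, 135 lost the call, 162 gained it and 8 turned direction. Among the called ones 147 kept their call under every alternative, and in BAT 12 of 73 lost it under at least 1. These 12 were Cidea, Cox7a1, Cox8b, Lpl, Pdk4, Retn, Lck, Nkg7, mt-Nd1, mt-Nd2, mt-Co1 and mt-Co3. The 8 that turned were Vegfa in BAT with library totals (-0.29), Slc27a2 in BAT with library totals (-0.27), with limma-voom (-0.0249) and without BAT_30C replicate 1 (-0.13, the left-out range reaching 0.32), mt-Nd2 in BAT with library totals (-0.0427), and Adrb3 in WAT with library totals (-0.0948), with limma-voom (-0.20) and without WAT_5C replicate 1 (-0.34, the range reaching 0.50). Depth limits genes at 0 counts in a group, whose ratio is bounded by a floor of 3 counts.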

Other observations

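Chosen after the results were seen in this part were the list results without WAT_5C replicate 1 and the naming of genes from that comparison. In cold brown fat, genes of protein and organelle turnover rose along with those of fuel use. Of the proteasome list 20 of 22 members rose and 0 fell (median 0.54, camera adjusted p = 3.13e-07, and adjusted p = 0.606 with an estimated correlation), with the same count adjusted over the list alone. Psmc4, of the regulatory cap, rose by 1.23 ± 0.07 (SE, adjusted p = 8.08e-07) and Psmb5, of the catalytic core, by 0.81 ± 0.05 (SE, adjusted p = 1.03e-06). Of the autophagy and lysosome list 16 of 18 rose (17 adjusted over the list alone) and 1 fell (median 0.54, camera adjusted p = 2.12e-05, and adjusted p = 0.606 with an estimated correlation). Under library totals, which lower the fold changes in BAT, 11 rose and 5 fell in the proteasome list and 8 and 4 in the autophagy and lysosome list. The protease gene Ctsd rose by 1.63, the lysosomal lipase gene Lipa by 1.65 and the membrane protein gene Lamp1 by 0.85. Of the glycogen list 8 of 12 rose and 1 fell (camera adjusted p = 0.00214, and adjusted p = 0.606 with an estimated correlation), with the same counts adjusted over the list alone, and the genes include both makers and breakers of glycogen. Pygl, a glycogen phosphorylase, rose by 2.91, Gbe1, the branching enzyme, by 2.02 and Ugp2, which makes UDP-glucose, by 2.35. In WAT without WAT_5C replicate 1, Gys2, a glycogen synthase, rose by 2.89 ± 0.35 (SE, adjusted p = 0.0153) and Ppp1r3b, which targets a phosphatase to glycogen, by 2.02 ± 0.29 (SE, adjusted p = 0.0208), whereas with all WAT libraries they stood at 3.49 (adjusted p = 0.0704) and 2.39 (adjusted p = 0.072).

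Serine and one-carbon genes moved apart in cold brown fat. 5 of 10 fell and 2 rose, with the same counts adjusted over the list alone and a camera adjusted p of 0.391. Phgdh, the first enzyme of serine synthesis, fell by 5.35 (adjusted p = 1.10e-06), Aldh1l2, of mitochondrial formate handling, by 2.58 and Shmt1, which converts serine to glycine, by 1.12. Psph, the last enzyme of serine synthesis, rose by 1.89 and the cytosolic Aldh1l1 by 1.63. By fry the list differed between the tissues in its cold effect (adjusted p = 0.000159), higher in WAT in 4 of 10 and lower in 1 (4 and 2 adjusted over the list alone, and 5 and 2 over all genes without WAT_5C replicate 1), while camera did not rank it apart from other genes (adjusted p = 0.263). Genes of cell division fell in 16 of 24 members in BAT and 2 rose (median -0.70, camera adjusted p = 0.0098, and adjusted p = 0.728 with an estimated correlation), with the same counts adjusted over the list alone. Branched-chain amino acid breakdown rose in 13 of 19 and fell in 3 (camera adjusted p = 0.00214, and adjusted p = 0.688 with an estimated correlation). The antioxidant list rose in 15 of 21 and fell in 2 (camera adjusted p = 0.000267, and adjusted p = 0.606 with an estimated correlation), again with the same counts adjusted over the list alone for both lists, while under library totals 8 rose and 6 fell for branched-chain amino acids, 12 and 6 for antioxidants, and 0 and 19 for cell division.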
